A study of Mus musculus with 30 samples.

How the data were processed

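Total RNA of whole salivary gland from female NOD.H-2h4 mice was profiled on 30 Affymetrix Mouse Genome 430 2.0 arrays. Each array measured labelled cRNA made from 2 ug of total RNA, per the labels. The mice had received 1 intraperitoneal dose of 20 mg/kg of anti-CD40L antibody or of a human IgG1 control antibody when 4 weeks old. Glands were taken at week 8, 16 or 24, which gave 6 groups of 5 arrays, described as biological replicates by the labels.

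The table of values was used as deposited. Its values were read as log2 intensities from their range of 2.757 to 14.457 in the deposited table, and the array medians lay between 5.487 and 5.537. The submitters' processing notes name limma, with no version. How probes were summarised and how arrays were normalised is not given in the sources used here. No value was missing, and every column of the table could be assigned to a sample. No logarithm or further normalization was applied.

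The table held 45101 probe sets, 64 of them array controls. A probe set was used when the platform table gave it exactly 1 gene, which held for 34958 probe sets, and 34754 of these had an Entrez identifier in the RefSeq table of genome build GRCm38.p6. A further 932 probe sets named several genes and 9211 were not named here. No gene symbol had to be updated. Of the 18193 genes with a probe set, each was represented by the probe set with the highest mean over the 30 arrays. A gene was tested when that probe set lay above the median of its own array in at least 5 arrays, in any groups, and 12998 genes were tested.

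A linear model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, and 9 contrasts were taken from it with moderated statistics. These were anti-CD40L against control at each of the 3 ages, weeks 16 and 24 against week 8 within each treatment, and the change of the treatment effect from week 8 to week 16 and from week 8 to week 24. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were counted. Errors beside log2 changes are standard errors from this model, with 5 arrays per group. The replicate numbers were not used to pair arrays.

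A set of 29 gene lists with 507 members was fixed for the cell types, pathways and gland products relevant to this tissue and treatment. Of these members 376 were tested, and 28 lists had the minimum of 5 tested members; the list of red blood cell genes, with 2, was left out. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The p values were adjusted over the 28 lists. The comparisons, the filter, the lists, the rule for named genes and most alternatives were chosen before the data were examined. For each comparison the rule names Cd40lg and Cd40, then the 8 largest rises and the 8 largest falls past the threshold. It adds the 4 members with the largest change of every list that passed camera or had at least 3 called members, and up to 2 members of any other list. About 20 to 30 genes per comparison are given in that order of priority. As an exception made after the values were seen, 2 kappa light chain variable genes that the rule names are not reported by name; they are included in every count, and in several comparisons one of them had the largest change. Other probe sets of a named gene that moved the opposite way are mentioned.

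Array quality was checked with the mean 3' minus 5' difference of the Gapdh and beta-actin control probe sets, on the log2 scale, with a spiked hybridization control, with Amy1 as a marker of parotid tissue and with the median correlation of each array with the others. These measures were compared between groups with two-sided exact permutation tests, adjusted over the family of 28 tests. The smallest p that 5 arrays against 5 can give is 0.00794. No pair of arrays was a duplicate, the highest correlation being 0.9919.

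The model was tested on simulated data of the same size, with log2 shifts of 0.5, 1 and 2 placed in 67, 67 and 66 of 12998 genes. For the treatment effect it recovered 43.3% to 53.7% of the smallest shifts, 88.1% to 98.5% of the middle and 98.5% to 100% of the largest. For the changes of the effect to weeks 16 and 24 it recovered less, 14.9% and 29.9% of the smallest, 62.7% and 71.6% of the middle and 100% and 92.4% of the largest. False calls were between 2.34% and 8.53% of all calls over the 9 comparisons. The shifted list was found, and 0 other lists were called, in each comparison. The simulated noise was drawn independently for each gene and array, with the residual spread of the gene. It lacks the correlation between genes and the unequal arrays of the real data. The rates of false calls of genes and lists therefore need not hold for the real arrays.

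The alternatives tried were quantile normalization, centring each array on its median, no filter, a stricter filter at the 70th percentile, the median over the probe sets of a gene, every probe set tested on its own, a model of only the groups compared, array weights, a moderated test with trend and robust estimation, a minimum fold change of 1.5, a threshold of 0.1, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were the 3' minus 5' difference as a covariate, the Amy1 level as a covariate, and leaving out the 5 arrays whose median correlation with the others was under 0.96. Probe sets with several genes or none were left out of the comparisons, because they could not be assigned to a gene.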

Results

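The study measured gene expression in whole salivary gland of NOD.H-2h4 mice, a strain that develops autoimmune inflammation, after 1 early dose of an antibody against CD40L. CD40L (gene Cd40lg) is a protein of activated T cells that binds CD40 on B cells and other antigen-presenting cells. Each of the 6 groups, anti-CD40L or control antibody at week 8, 16 or 24, had 5 arrays, and this number limits the precision. Values are on the log2 scale, so a change of 1 is a doubling. The standard error of a treatment difference had a median of 0.139 over the 12998 genes tested.

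Of the target pair, Cd40lg was low in these glands and Cd40 was above the filter. Cd40lg had a mean log2 level of 4.92 in week 8 controls and 4.91 after anti-CD40L, and no group mean was above 4.92. It was therefore under the filter and was not tested. Cd40 averaged 6.70, 6.32 and 6.68 in controls at weeks 8, 16 and 24 and 6.47, 5.91 and 6.09 after anti-CD40L.

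The 3' minus 5' difference of the control transcripts, a measure of RNA quality that increases as RNA degrades, was not even over the groups. In controls it averaged 0.566 (SD 0.198), 0.291 (SD 0.0661) and 0.406 (SD 0.121) at weeks 8, 16 and 24. After anti-CD40L it averaged 0.369 (SD 0.0984), 0.260 (SD 0.0481) and 0.20 (SD 0.0359), n = 5 each. The level of Amy1, the parotid amylase, ranged from 6.575 to 13.695 over the 30 arrays.

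**Figure D1:**
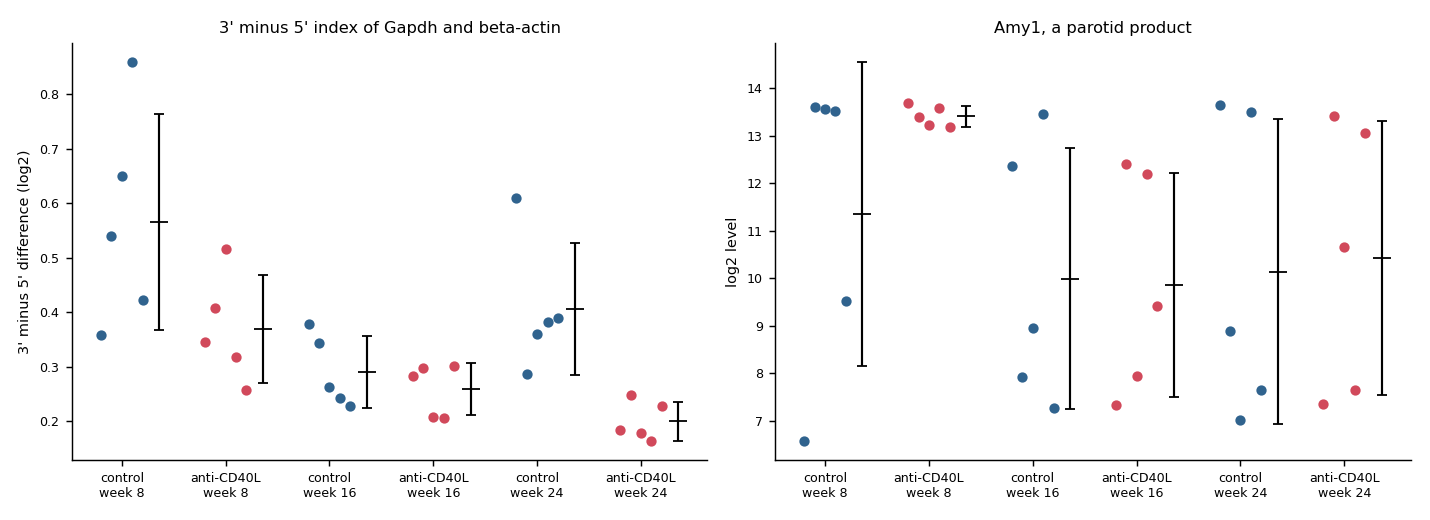
The left panel plots the 3' minus 5' difference (log2) of each array and the right panel the log2 level of Amy1, by treatment (blue control, red anti-CD40L) and age in weeks. At week 24 every anti-CD40L array lies below every control array in the 3' minus 5' difference, and Amy1 is above 13 in all week 8 anti-CD40L arrays.

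At week 8, the first comparison asks what the antibody had changed 4 weeks after the dose. Immunoglobulin transcripts were lower in the treated glands. Jchain, the chain that joins IgA and IgM into polymers, fell by 2.56 ± 0.34 (log2 ± SE, n = 5 per group, adjusted p = 0.00018), and the light chain variable gene Igkv8-30 fell by 2.32 ± 0.29 (adjusted p = 0.000148). Igha, the IgA heavy chain, changed by -1.69 ± 0.27 (adjusted p = 0.00291) and the kappa light chain Igk by -1.33 ± 0.23 (adjusted p = 0.00954). In each of these genes all 5 treated arrays lay below all 5 controls. Of the 6 immunoglobulin genes tested, 3 fell, or 4 when adjusted over the list alone, and none rose (list median -1.51, camera adjusted p = 1.39e-08; adjusted p = 0.0592 with an estimated correlation).

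In total 9 of 12998 genes passed at week 8, 0 higher and 9 lower, while 2019 had an unadjusted p under 0.05 in limma. The split was not stable: array weights gave 25 higher and 18 lower, and leaving out the 5 arrays of low correlation, chosen after the data were seen, gave 25 higher and 11 lower. The other genes that fell were Ezhip (-0.90 ± 0.18, adjusted p = 0.0417), Zfp938 (-0.68 ± 0.12, adjusted p = 0.0187), Ppp1r11 (-0.57 ± 0.11, adjusted p = 0.0339; another of its probe sets gave 0.23), Cep112 (-0.54 ± 0.10, adjusted p = 0.0298) and 2810410L24Rik (-0.52 ± 0.10, adjusted p = 0.0298), the last named after its value was seen. Ezhip inhibits the Polycomb histone methyltransferase. Cd40 did not pass (-0.23 ± 0.16, adjusted p = 0.474), nor did Mzb1, a chaperone of antibody-secreting cells (-0.97 ± 0.34, adjusted p = 0.236), the B cell antigen Ms4a1 (-0.36 ± 0.59) or the T cell receptor component Cd3d (-0.36 ± 0.46). Among the 18 fibroblast and matrix genes 16 were above 0 without any passing, adjusted over the list alone included, and the list passed with a median of 0.21 (camera adjusted p = 0.0192; adjusted p = 0.957 with an estimated correlation). Its largest values were for the collagens Col1a1 (0.63 ± 0.28, adjusted p = 0.294) and Col1a2 (0.58 ± 0.24, adjusted p = 0.27). The 3' minus 5' difference was lower by 0.197 in the treated arrays (exact permutation p = 0.0635, adjusted p = 0.127).

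No gene passed at week 8 when only the 10 arrays compared were fitted, where Jchain and Igkv8-30 gave adjusted p = 0.156 and Igha, Igk, Ezhip, Zfp938, Ppp1r11 and Cep112 gave 0.628. In the model of all arrays, Jchain, Igkv8-30 and Igha kept their call without any 1 of the 10. Ezhip lost it without 7 of them (highest adjusted p = 0.151, without anti-CD40L replicate 4), Ppp1r11 without 6 (0.134, same array), Zfp938 and Cep112 without 5 (0.0941 and 0.128, without control replicate 4) and Igk without 1 (0.0512, without anti-CD40L replicate 5). The count was 23 and 5 without control replicates 1 and 3, and 4 without each of anti-CD40L replicates 2, 4 and 5.

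At week 16, the question was whether the difference held at an older age. Antibody transcripts were again lower, and the transcripts of dividing cells were higher. The kappa variable gene Igkv6-20 changed by -3.40 ± 0.53 (adjusted p = 0.000509), Jchain by -3.34 ± 0.34 (adjusted p = 7.34e-07) and the lambda gene Iglv1 by -3.27 ± 0.49 (adjusted p = 0.000401). Igkv6-14 and Igkv8-30 changed by -2.91 ± 0.45 and -2.65 ± 0.29. Every treated array lay below every control array for these 5 genes. Of the 6 tested members of the immunoglobulin list 4 fell, and 4 when adjusted over the list alone (median -2.24, camera adjusted p = 2.49e-14; adjusted p = 0.00511 with an estimated correlation). Among them were Igk (-2.44 ± 0.23, adjusted p = 2.71e-07) and Igha (-2.03 ± 0.27, adjusted p = 5.14e-05). Of 12 plasma cell genes 3 fell and 2 rose, 6 and 2 when adjusted over the list alone (median -0.39, camera adjusted p = 0.000359; adjusted p = 0.129 with an estimated correlation). Mzb1 (-2.32 ± 0.34, adjusted p = 0.000358) and Tnfrsf17, the BCMA receptor of plasma cells (-0.82 ± 0.21, adjusted p = 0.0374), fell. Edem1 (0.57 ± 0.15, adjusted p = 0.0401) and Fkbp11 (0.52 ± 0.14, adjusted p = 0.0457), which rose, encode proteins of the endoplasmic reticulum that other secretory cells also make; both were named after their values were seen.

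Some MHC class II transcripts were also lower at week 16. Of 10 genes 3 fell, or 6 when adjusted over the list alone (median -1.07, camera adjusted p = 2.08e-09; adjusted p = 0.14 with an estimated correlation). These were H2-Eb1 (-1.61 ± 0.42, adjusted p = 0.0408), H2-Aa (-1.60 ± 0.38, adjusted p = 0.0299) and the invariant chain Cd74 (-1.54 ± 0.38, adjusted p = 0.0357), each lower in all 5 treated arrays than in any control. No B cell or T cell gene passed, also when adjusted over the list alone, although all 15 B cell genes lay below 0 (median -0.29, camera adjusted p = 0.000192) and the T cell median was -0.35 (camera adjusted p = 0.00156). Both lists gave adjusted p = 0.202 with an estimated correlation. In control replicates 1 and 4 the B cell level was 6.278 and 6.482 and the T cell level 6.787 and 6.879. In the other controls these were 5.518 to 5.573 and 5.986 to 6.067, and in treated arrays 5.38 to 5.57 and 5.86 to 6.08. Cd79b, a signalling chain of the B cell receptor, gave -0.87 ± 0.36 (adjusted p = 0.24), Ms4a1 -0.97 ± 0.59, Cd3g -1.15 ± 0.54 and Cd40 -0.41 ± 0.16 (adjusted p = 0.198).

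Without a single gene past the threshold, the lists of interferon gamma response genes (19 of 19 below 0, median -0.54, camera adjusted p = 2.75e-08), cytotoxic T and NK cell genes (median -0.74, camera adjusted p = 1.53e-06), macrophage and dendritic cell genes (median -0.27, camera adjusted p = 7.65e-05) and CD40 and NF-kB response genes (median -0.15, camera adjusted p = 0.0148) were lower. With an estimated correlation these gave adjusted p = 0.225, 0.14, 0.225 and 0.202. Adjusted over the list alone, 0 of 19, 5 of 10, 2 of 19 and 0 of 12 members fell. Examples are the chemokine Cxcl9 (-2.01 ± 0.84, adjusted p = 0.245), Nkg7 of cytotoxic granules (-1.08 ± 0.36, adjusted p = 0.12) and the myeloid adaptor Tyrobp (-0.85 ± 0.25, adjusted p = 0.0708). The mean interferon gamma level was 8.733 and 8.502 in control replicates 1 and 4. It was 6.864 to 7.131 in the other controls and 6.58 to 7.32 in treated arrays. Control replicates 1 and 4 were highest in the other lists named here. Amy1 was 12.375 and 13.454 there and 7.271 to 8.95 in the other controls. With Amy1 at 12.407 and 12.206, treated replicates 2 and 4 had interferon gamma levels of 6.866 and 7.285. Parotid tissue as a cause was not tested. Of 8 lymphoid tissue chemokine and stroma genes 1 fell, also when adjusted over the list alone (median -0.30, camera adjusted p = 0.0178; adjusted p = 0.202 with an estimated correlation). It was Cxcl12 (-0.63 ± 0.17, adjusted p = 0.0455), the CXCR4 ligand, of which 1 of the 2 other probe sets had the opposite sign (0.65).

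The cell division list rose at week 16 by camera. Of 19 genes 4 rose, or 17 when adjusted over the list alone, and none fell (median 1.13, camera adjusted p = 2.49e-14; adjusted p = 0.14 with an estimated correlation). The median was 0.67 without anti-CD40L week 16 replicate 5, and 2 to 13 members passed without 1 treated array. Birc5, or survivin, rose by 2.08 ± 0.50 (adjusted p = 0.0299) and the kinase Cdk1 by 1.93 ± 0.39 (adjusted p = 0.00816), each above all controls in 4 of the 5 treated arrays. The other called members, Aurka (1.48 ± 0.32, adjusted p = 0.0135) and Ccna2 (1.38 ± 0.35, adjusted p = 0.0374), were named after their values were seen. The mean level of the list varied from 6.16 to 9.04 between the treated arrays (mean 7.44, SD 1.05) against a control mean of 6.31 (SD 0.20). Other large rises were the muscle Z-disc protein Myot (2.35 ± 0.36, adjusted p = 0.000401), the thyroid hormone carrier Ttr (2.29 ± 0.57, adjusted p = 0.0356), Lypd6b (1.99 ± 0.39, adjusted p = 0.00718), the mitotic kinase Pbk (1.96 ± 0.49, adjusted p = 0.0371) and the glutathione peroxidase Gpx2 (1.96 ± 0.35, adjusted p = 0.0024).

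Clock genes moved in opposite directions at week 16. Arntl, the BMAL1 activator of the circadian clock, rose by 2.08 ± 0.31 (adjusted p = 0.000401), and Dbp, Tef, Per3 and Nr1d2, which peak at the other phase, changed by -3.02 ± 0.61, -1.11 ± 0.22, -1.13 ± 0.30 and -0.87 ± 0.14 (adjusted p = 0.00772, 0.00768, 0.0476 and 0.00109). All treated arrays were beyond all controls, except for Per3 with 4 of 5. Of 16 clock genes 1 rose and 4 fell, 2 and 9 when adjusted over the list alone (median -0.38, camera adjusted p = 9.74e-05; adjusted p = 0.14 with an estimated correlation). Lists of tissue genes were lower as well. Among 18 fibroblast and matrix genes 2 fell, Lum (lumican; -1.11 ± 0.27, adjusted p = 0.0344) and Col6a3 (-0.63 ± 0.16, adjusted p = 0.0414), and 9 fell and 1 rose when adjusted over the list alone (median -0.38, camera adjusted p = 3.08e-07; adjusted p = 0.14 with an estimated correlation). None of 11 granular duct products passed, 2 fell when adjusted over the list alone (median -0.27, camera adjusted p = 2.44e-05), and none of 13 myoepithelial and smooth muscle genes passed either way (median -0.23, camera adjusted p = 0.0257). These lists gave adjusted p = 0.225 and 0.425 with an estimated correlation. Of the 13 other lists, which did not pass, S100a8 (1.37 ± 0.34, adjusted p = 0.0357) rose in the neutrophil list and Folr1, a folate receptor (0.92 ± 0.14, adjusted p = 0.000449), in the acinar list, while Dnajb9, an endoplasmic reticulum chaperone (-0.77 ± 0.14, adjusted p = 0.00361), fell in the unfolded protein response list.

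**Figure D2:**
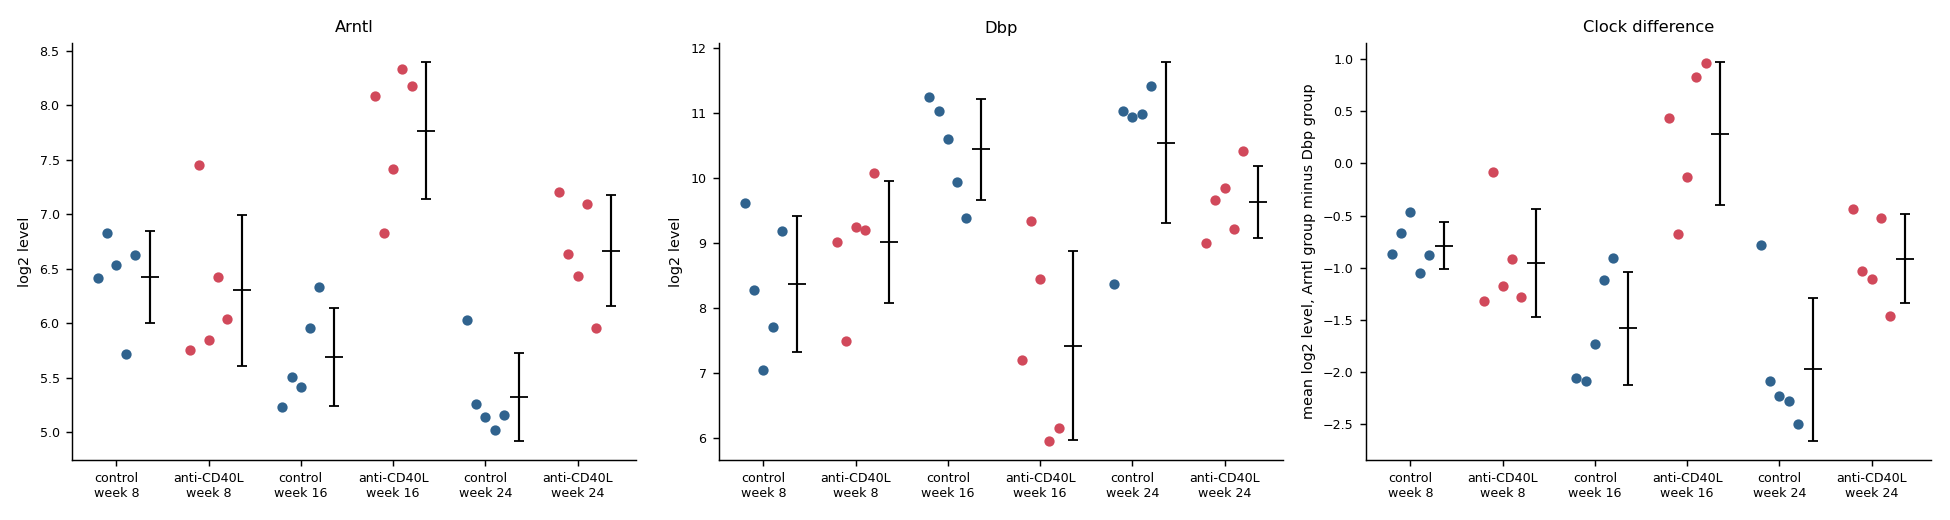
The panels plot the log2 level of Arntl, the log2 level of Dbp, and the clock difference (mean log2 level of genes in phase with Arntl minus that of genes in phase with Dbp) in each array, by age in weeks, for control (blue) and anti-CD40L (red). At week 16 the clock difference averages 0.28 after anti-CD40L and -1.58 in controls, without overlap of arrays.

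In total 245 genes passed at week 16, 170 higher and 75 lower, and 1910 had an unadjusted p under 0.05. Fitting only the 10 arrays compared gave 965, ending the calls of Birc5 (adjusted p = 0.0688), Pbk (0.085) and H2-Eb1 (0.0539), and array weights gave 1557. After quantile normalization 278 passed, 153 higher and 125 lower. The 3' minus 5' difference was similar in both groups at this age (0.260 and 0.291, exact permutation p = 0.413). The count was 86, 111, 122 and 74 without control replicates 1, 2, 3 and 4, and 144 and 78 without anti-CD40L replicates 4 and 5. The call ended without 9 of the 10 arrays for Ttr (highest adjusted p = 0.113, without anti-CD40L replicate 4) and Cxcl12 (0.128, control replicate 4), without 8 for Pbk (0.141, anti-CD40L replicate 5) and Per3 (0.161, control replicate 1), and without 7 for Tnfrsf17 (0.122, control replicate 1) and S100a8 (0.141, anti-CD40L replicate 5). It ended without 6 for Birc5 (0.11, anti-CD40L replicate 5), H2-Eb1 (0.149, control replicate 4) and Lum (0.103, anti-CD40L replicate 4), and without 4 for H2-Aa and Cd74 (0.111 and 0.128, anti-CD40L replicate 5).

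At week 24, the last age, the comparison asks how the treated gland differed from controls of the same age. B cell and T cell transcripts were then lower beside the antibody transcripts. Ighm, the IgM heavy chain, changed by -3.98 ± 0.77 (adjusted p = 0.00429) and Ms4a1 (CD20) by -3.70 ± 0.59 (adjusted p = 0.000887). Igkv6-20 changed by -3.30 ± 0.53 (adjusted p = 0.00107), Igkv6-14 by -3.27 ± 0.45 (adjusted p = 0.000149) and Iglv1 by -2.83 ± 0.49 (adjusted p = 0.00197). Of 15 B cell genes 11 fell and none rose, and 11 when adjusted over the list alone (median -0.98, camera adjusted p = 4.86e-12; adjusted p = 0.0267 with an estimated correlation). They included Cd79b (-2.59 ± 0.36, adjusted p = 0.000149), H2-Ob (-2.60 ± 0.55, adjusted p = 0.00691), which tunes peptide loading in B cells, and the adaptor Bank1 (-1.77 ± 0.36, adjusted p = 0.00651). In all of these every treated array lay below every control.

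Of the 6 immunoglobulin genes 5 fell, and 5 when adjusted over the list alone (median -2.20, camera adjusted p = 3.15e-08; adjusted p = 0.0274 with an estimated correlation). Jchain was at -1.80 ± 0.34 (adjusted p = 0.00335). Of 12 plasma cell genes 6 fell, and 6 when adjusted over the list alone (median -0.46, camera adjusted p = 5.98e-06; adjusted p = 0.0267 with an estimated correlation). Among them were Mzb1 (-2.62 ± 0.34, adjusted p = 0.000119), the APRIL and BAFF receptor Tnfrsf13b (-1.40 ± 0.21, adjusted p = 0.000369) and Tnfrsf17 (-1.15 ± 0.21, adjusted p = 0.00247). Of 11 T cell genes 6 fell, or 9 when adjusted over the list alone (median -0.59, camera adjusted p = 3.12e-07; adjusted p = 0.0436 with an estimated correlation). Examples are Cd3d (-2.31 ± 0.46, adjusted p = 0.00576), Cd3g (-2.15 ± 0.54, adjusted p = 0.0165), the adhesion receptor Cd2 (-1.70 ± 0.35, adjusted p = 0.00667) and the signalling adaptor Lat (-1.08 ± 0.24, adjusted p = 0.01). Ms4a4b, also a T cell gene, fell by 2.60 ± 0.59 (adjusted p = 0.0106).

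**Figure D3:**
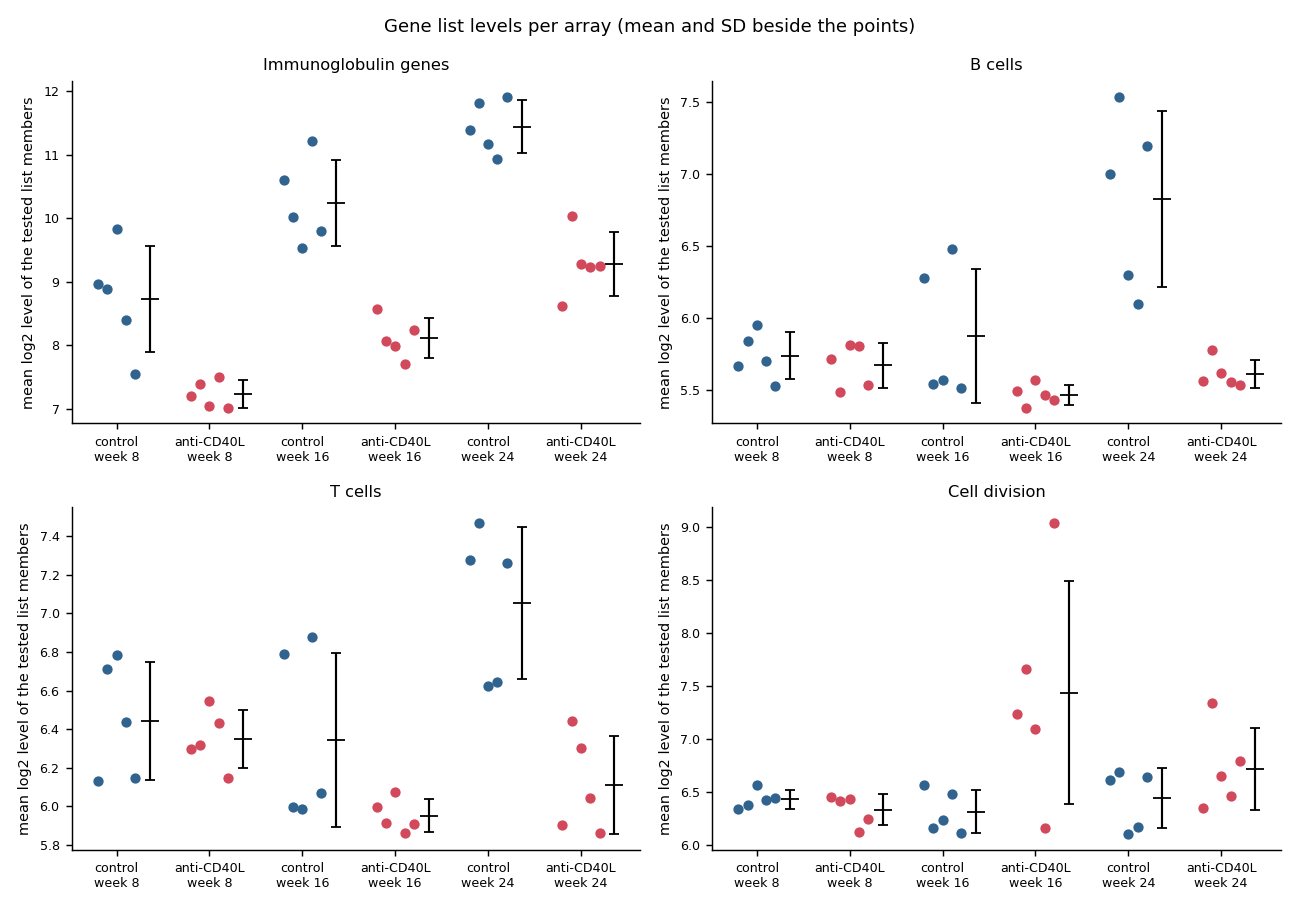
Each panel plots the mean log2 level of the tested members of 1 list (immunoglobulin genes, B cells, T cells, cell division) in each array, by age in weeks, for control (blue) and anti-CD40L (red), with the group mean and SD beside the points. The B cell mean goes from 5.74 to 6.83 in controls between weeks 8 and 24 and is 5.61 in week 24 anti-CD40L arrays.

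Some transcripts of lymphoid chemokines, of the CD40 and NF-kB response and of MHC class II were lower at week 24. Of 8 lymphoid chemokine and stroma genes 3 fell, and 3 when adjusted over the list alone (median -0.36, camera adjusted p = 0.00645; adjusted p = 0.195 with an estimated correlation). These were lymphotoxin beta (Ltb, -1.96 ± 0.39, adjusted p = 0.00566), the follicle chemokine Cxcl13 (-1.38 ± 0.38, adjusted p = 0.0262) and BAFF (Tnfsf13b, -0.49 ± 0.16, adjusted p = 0.0456). Of 12 genes of the CD40 and NF-kB response 3 fell, or 4 when adjusted over the list alone (median -0.23, camera adjusted p = 0.000251; adjusted p = 0.0639 with an estimated correlation). These were the activation marker Cd83 (-1.44 ± 0.32, adjusted p = 0.00869), Traf1 (-0.63 ± 0.18, adjusted p = 0.0312) and Cd40 itself (-0.59 ± 0.16, adjusted p = 0.0229), each with 4 or more treated arrays under all controls. Of 10 MHC class II genes 5 fell, or 8 when adjusted over the list alone (median -0.89, camera adjusted p = 9.18e-07; adjusted p = 0.197 with an estimated correlation). Examples are H2-DMb2 (-1.72 ± 0.34, adjusted p = 0.00439) and H2-Oa (-1.07 ± 0.27, adjusted p = 0.0175).

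Interferon and effector lists fell by camera with few gene calls. Of 20 type I interferon genes 2 fell, or 5 when adjusted over the list alone (median -0.44, camera adjusted p = 0.000251; adjusted p = 0.413 with an estimated correlation). Among them was the antiviral sensor Oas1a (-1.31 ± 0.29, adjusted p = 0.00981). Of 19 interferon gamma genes 3 fell, or 5 when adjusted over the list alone (median -0.59, camera adjusted p = 9.16e-07; adjusted p = 0.268 with an estimated correlation). They included the immunoproteasome subunits Psmb8 (-1.29 ± 0.38, adjusted p = 0.0342) and Psmb9 (-1.22 ± 0.37, adjusted p = 0.0376). Of 10 cytotoxic cell genes the NK receptors Klrd1 (-1.60 ± 0.51, adjusted p = 0.046) and Klrk1 (-0.82 ± 0.24, adjusted p = 0.0355) fell, 6 when adjusted over the list alone (median -0.62, camera adjusted p = 7.07e-05; adjusted p = 0.197 with an estimated correlation). Of 19 macrophage and dendritic cell genes Ms4a7 (-0.96 ± 0.29, adjusted p = 0.0402) and Tyrobp (-0.85 ± 0.25, adjusted p = 0.0326) fell, and 5 fell and 3 rose when adjusted over the list alone (median -0.25, camera adjusted p = 0.032; adjusted p = 0.526 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.0561). No neutrophil gene passed either way (11 genes, median -0.26, camera adjusted p = 0.00645; adjusted p = 0.197 with an estimated correlation).

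Ductal, acinar and fibroblast lists were higher at week 24 by camera, and none of these calls held with an estimated correlation. Of 20 ductal genes 5 rose and none fell, 9 when adjusted over the list alone (median 0.40, camera adjusted p = 4.43e-05; adjusted p = 0.197 with an estimated correlation). Foxi1, the regulator of ionocytes, rose by 1.26 ± 0.22 (adjusted p = 0.00217), the sodium-proton exchanger Slc9a3 by 0.87 ± 0.21 (adjusted p = 0.0149) and the epithelial regulator Elf5 by 0.68 ± 0.12 (adjusted p = 0.00197), with 4, 3 and 5 treated arrays above all controls. Of 19 acinar genes 2 rose, 4 when adjusted over the list alone (median 0.19, camera adjusted p = 0.00267; adjusted p = 0.197 with an estimated correlation). They were Bhlha15, the secretory cell regulator MIST1 (0.77 ± 0.19, adjusted p = 0.0134), and Folr1 (0.50 ± 0.14, adjusted p = 0.0305). Of 18 fibroblast and matrix genes 3 rose, 7 when adjusted over the list alone (median 0.25, camera adjusted p = 0.00836; adjusted p = 0.414 with an estimated correlation). They included the receptor Pdgfra (0.74 ± 0.16, adjusted p = 0.00819) and Col1a2 (0.84 ± 0.24, adjusted p = 0.0319). Of 9 skeletal muscle genes Pvalb (parvalbumin, -0.92 ± 0.22, adjusted p = 0.0133) and Tcap (-0.65 ± 0.12, adjusted p = 0.00335) fell, 4 when adjusted over the list alone (median -0.54, camera adjusted p = 0.000251; adjusted p = 0.184 with an estimated correlation). Among the largest rises were the proline-rich salivary protein Prp2 (1.64 ± 0.51, adjusted p = 0.0431), the nuclear receptor Nr4a2 (1.59 ± 0.28, adjusted p = 0.00226; 2 of 5 other probe sets were of opposite sign), the epidermal factor Kdf1 (1.55 ± 0.44, adjusted p = 0.0301), the mitochondrial coactivator Ppargc1a (1.48 ± 0.25, adjusted p = 0.0015) and the tight junction protein Cldn1 (1.45 ± 0.32, adjusted p = 0.00904).

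The other 12 lists tested at week 24 did not pass, among them the naive lymphocyte and lymph node macrophage list (median -0.38, camera adjusted p = 0.051), germinal centre genes (median -0.16, camera adjusted p = 0.0917) and parotid products (median -0.28, camera adjusted p = 0.139). The cell division list did not pass at this age, with 17 of 19 members above 0 (median 0.30, camera adjusted p = 0.247). Of 16 clock genes 2 rose and 1 fell (median -0.11, camera adjusted p = 0.341): Arntl (1.34 ± 0.31, adjusted p = 0.0115; its other probe set gave -0.14), Clock (0.76 ± 0.24, adjusted p = 0.0435) and Ciart (-0.89 ± 0.24, adjusted p = 0.0223).

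**Figure D4:**
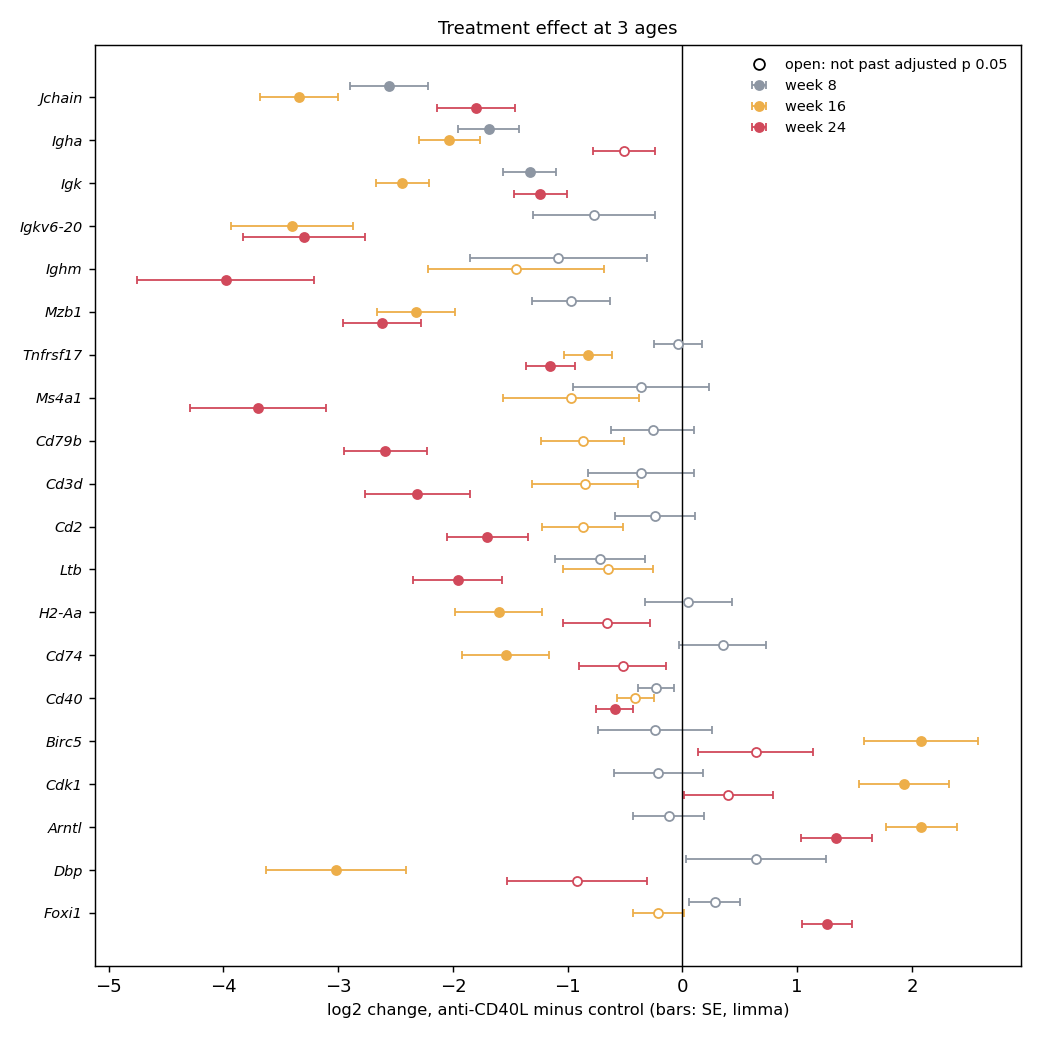
Log2 change ± SE of 20 genes, anti-CD40L minus control, at weeks 8, 16 and 24; open points did not pass adjusted p 0.05, and the genes were chosen for the plot after their values were seen. Jchain is at -2.56, -3.34 and -1.80, while Ms4a1 passed at week 24 alone (-3.70).

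In total 1229 genes passed at week 24, 775 higher and 454 lower, and 3853 had an unadjusted p under 0.05. After quantile normalization 1304 passed, 630 higher and 674 lower. RNA quality differed between these groups, with a 3' minus 5' difference of 0.20 after anti-CD40L against 0.406 in controls and no overlap of arrays (exact permutation p = 0.00794, adjusted p = 0.0278). With this measure as a covariate 23 genes passed, 5 higher and 18 lower, all of them among the 1229, and the falls of Igkv6-14 (-3.30), Ms4a1 (-3.15), Cd79b (-2.49) and Mzb1 (-2.26) were among those that passed. The median of the 775 rises went from 0.59 to 0.30 and that of the 454 falls from -0.54 to -0.40, while the median standard error went from 0.139 to 0.145. The ductal median went from 0.40 to 0.09 and the acinar median from 0.19 to 0.05.

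Fitting only the 10 arrays of week 24 gave 129 genes, 72 higher and 57 lower, and ended 28 of the 49 named calls (adjusted p = 0.052 to 0.109). In the model of all arrays the week 24 count was 237, 2140, 514 and 1933 without control replicates 1, 2, 3 and 4, and 527, 698, 397 and 676 without anti-CD40L replicates 1, 3, 4 and 5. Calls ended without 8 of the 10 arrays for Prp2, Klrd1, Psmb9, Tnfsf13b and Clock, and without 7 for Psmb8. They ended without 6 for Kdf1, Traf1, Klrk1, Ms4a7 and Tyrobp, and without 5 for Cd40, Col1a2 and Folr1. They ended without 4 for Cxcl13 and Ciart, and without control replicate 1 alone for Cd3g, Bhlha15, Slc9a3, H2-Oa and Ms4a4b. Control replicate 1 ended most of these calls (highest adjusted p = 0.213, Klrd1).

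The genes past the threshold were compared between ages. The falls at weeks 8 and 16 shared Igha, Igkv8-30, Jchain and Igk, 4 genes against 0.0519 for independent sets (one-sided Fisher's exact p = 1.26e-07). The falls at weeks 8 and 24 shared Igkv8-30, Jchain, Igk and Ppp1r11 (0.314 by independence, exact p = 0.000161). The falls at weeks 16 and 24 shared 17 genes (2.62 by independence, exact p = 5.84e-10), and the rises shared 12 (10.1 by independence, exact p = 0.315). Over all 9 comparisons, the camera calls that held with an estimated correlation were immunoglobulin genes at week 16, B cells, immunoglobulin genes, plasma cells and T cells at week 24, immunoglobulin genes and plasma cells between weeks 8 and 24 in controls, and B cells, plasma cells, T cells, naive lymphocytes and the CD40 and NF-kB response in the change of the treatment effect from week 8 to week 24.

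The comparison of ages in controls asks which genes changed with age without the treatment. From week 8 to week 16 antibody transcripts and secretory stress genes rose. Igkv6-20 rose by 3.12 ± 0.53 (adjusted p = 0.00012), Igha by 2.8 ± 0.27 (adjusted p = 3.78e-07) and Igkv6-14 by 2.72 ± 0.45 (adjusted p = 8.78e-05), with all week 16 arrays above all week 8 arrays. Of 6 immunoglobulin genes 4 rose, and 4 when adjusted over the list alone (median 2.04, camera adjusted p = 0.0388). This list gave adjusted p = 0.875 with an estimated correlation. Of 18 genes of the unfolded protein response 15 rose and Trib3, a pseudokinase induced by stress, was the 1 that fell (-0.45), with the same numbers adjusted over the list alone (median 0.55, camera adjusted p = 0.000158; adjusted p = 0.875 with an estimated correlation). Atf6, a stress sensor of the endoplasmic reticulum, rose by 1.30 ± 0.19 (adjusted p = 4.19e-05) and Sel1l by 1.13 ± 0.19 (adjusted p = 9.81e-05). Of 20 ductal genes 9 rose, and 9 when adjusted over the list alone (median 0.34, camera adjusted p = 0.0467; 0.875 with an estimated correlation), such as Kit (1.17 ± 0.23, adjusted p = 0.000334) and Foxi1 (1.12 ± 0.22, adjusted p = 0.000394). Of 18 fibroblast and matrix genes 9 rose, 10 when adjusted over the list alone (median 0.41, camera adjusted p = 0.0467; 0.875 with an estimated correlation), with Col1a1 at 1.12 ± 0.28 and Col1a2 at 1.0 ± 0.24.

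Of 16 clock genes 11 rose in controls from week 8 to week 16, 12 rising and 2 falling when adjusted over the list alone (median 0.67, camera adjusted p = 0.0467; adjusted p = 0.875 with an estimated correlation), including Dbp (2.07 ± 0.61, adjusted p = 0.00789) and Bhlhe40 (1.17 ± 0.23, adjusted p = 0.000357). Other large rises were the deubiquitinase Usp2 (2.64 ± 0.54, adjusted p = 0.000537) and the transcription factor Nfix (2.35 ± 0.58), and large falls were 5530400C23Rik (-3.54 ± 0.48, adjusted p = 2.41e-05), which has no established function, and the keratin Krt13 (-1.57 ± 0.43, adjusted p = 0.00504). All 10 MHC class II genes lay above 0 and 5 rose, without a list call. Cd74 rose by 1.60 ± 0.38 (adjusted p = 0.00186). Cd40 changed by -0.38 ± 0.16 (adjusted p = 0.0473), a call that ended without 7 of the 10 arrays (highest adjusted p = 0.118, without control week 16 replicate 3). In total 6046 genes passed, 3689 higher and 2357 lower, and after quantile normalization 6235, with 2619 higher and 3616 lower. The 3' minus 5' difference was 0.291 at week 16 and 0.566 at week 8 (exact permutation p = 0.0159, adjusted p = 0.0445). With it as a covariate 620 genes passed, 547 of them among the 6046.

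From week 8 to week 24 in controls, many B cell, antibody and MHC class II genes and some interferon genes rose. Igkv6-14 rose by 4.27 ± 0.45 (adjusted p = 7.08e-07), Ighm by 3.66 ± 0.77 (adjusted p = 0.00387), Prg2, the major basic protein of eosinophils, by 2.85 ± 0.22 (adjusted p = 3.02e-09) and Ms4a1 by 2.84 ± 0.59 (adjusted p = 0.00337). All 6 immunoglobulin genes rose, also when adjusted over the list alone (median 2.75, camera adjusted p = 6.14e-10; adjusted p = 0.0154 with an estimated correlation). Of 12 plasma cell genes 6 rose, 10 when adjusted over the list alone (median 0.50, camera adjusted p = 1.51e-06; adjusted p = 0.0154 with an estimated correlation). Mzb1 was at 2.73 ± 0.34 and Tnfrsf13b at 1.77 ± 0.21. Of 15 B cell genes 11 rose, and 11 when adjusted over the list alone (median 0.92, camera adjusted p = 3.89e-07; adjusted p = 0.149 with an estimated correlation). Cd79b was at 2.26 ± 0.36 and H2-Ob at 2.64 ± 0.55. All 10 MHC class II genes rose, also when adjusted over the list alone (median 1.46, camera adjusted p = 9.85e-08; adjusted p = 0.262 with an estimated correlation). H2-Ab1 rose by 1.84 ± 0.41. Of 20 type I interferon genes 7 rose, 13 when adjusted over the list alone (median 0.76, camera adjusted p = 5.17e-06). Ifit1 rose by 2.09 ± 0.51 and Oas1a by 1.45 ± 0.29. Of 19 interferon gamma genes 5 rose, 16 when adjusted over the list alone (median 0.81, camera adjusted p = 3.31e-06). Both gave adjusted p = 0.353 with an estimated correlation.

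Some T cell genes rose, with fewer calls, between weeks 8 and 24 in controls. Cd3g (2.11 ± 0.54, adjusted p = 0.012), Cd3d (1.71 ± 0.46, adjusted p = 0.0169) and Cd2 (1.57 ± 0.35, adjusted p = 0.00594) were the 3 of 11 that rose, 4 when adjusted over the list alone (median 0.28, camera adjusted p = 0.0392; adjusted p = 0.415 with an estimated correlation). Camera also passed macrophages (7 of 19 rose, C1qa by 0.87 ± 0.22), the unfolded protein response (7 of 18), myoepithelium and smooth muscle (5 of 13, Krt14 by 0.68 ± 0.13), skeletal muscle (4 of 9), the CD40 and NF-kB response (5 of 12), lymphoid chemokines (3 of 8, Cxcl13 by 1.22 ± 0.38), granular duct products (1 of 11) and clock genes (6 rose and Arntl fell, -1.10 ± 0.31). Adjusted over the list alone the members that rose were 10, 12, 6, 6, 6, 3, 7 and 6 in that order, with Arntl again the 1 that fell. Their camera adjusted p values were 0.000564, 0.000385, 0.00408, 0.0195, 0.0404, 0.0348, 0.025 and 0.0164, and adjusted p = 0.353 with an estimated correlation in each except granular duct products (0.533). Of 24 respiratory chain genes 3 fell, and 3 when adjusted over the list alone, such as Ndufa2 (-0.39 ± 0.10), with a list median of -0.04 (camera adjusted p = 0.0387; adjusted p = 0.477 with an estimated correlation; 0.268 after quantile normalization). Falls outside the lists were 5530400C23Rik (-5.40 ± 0.48), Nfil3, a repressor of clock output (-1.37 ± 0.28), and the imprinted gene Peg3 (-1.30 ± 0.19), and the mucin-like Smgc fell by 1.15 ± 0.15. Cd40 did not pass (-0.02 ± 0.16, adjusted p = 0.933).

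In total 1624 genes passed between weeks 8 and 24 in controls, 1103 higher and 521 lower, and 1838 after quantile normalization, 859 higher and 979 lower. The 3' minus 5' difference was 0.406 and 0.566 at weeks 24 and 8 (exact permutation p = 0.159). With it as a covariate 715 genes passed, 561 of them among the 1624. Fitting only the 10 arrays compared gave 41 genes, 33 higher and 8 lower, and ended 13 of the 22 named calls (adjusted p = 0.0578 to 0.147). The count was 2780 and 768 without control week 8 replicates 1 and 4, and 3228 and 721 without control week 24 replicates 1 and 2. Without control week 24 replicate 2 the adjusted p was 0.125 for Cxcl13, 0.0677 for Cd3d and 0.0549 for Arntl.

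In the treated glands, the comparison of ages asks which of these changes went on after the antibody. From week 8 to week 16 Igha rose by 2.46 ± 0.27 (adjusted p = 6.68e-06) and Igkv8-30 by 2.09. By camera the unfolded protein response and cell division lists rose and the T cell and parotid lists fell. None of the 4 held with an estimated correlation (adjusted p = 0.897 each). Of 18 unfolded protein response genes 13 rose and 1 fell, the same adjusted over the list alone (median 0.59, camera adjusted p = 0.000167), with Hyou1 at 0.98 ± 0.13 and Calr at 0.89 ± 0.11. Of 19 cell division genes 14 rose and 1 fell, 15 and 1 when adjusted over the list alone (median 1.28, camera adjusted p = 0.00295; adjusted p = 0.897 with an estimated correlation), with Birc5 at 2.03 ± 0.50, Mki67 at 1.98 ± 0.44 and Cdk1 at 1.72 ± 0.39. Of 11 T cell genes 3 fell, and 3 when adjusted over the list alone (median -0.38, camera adjusted p = 0.0166; 0.897 with an estimated correlation), among them the kinase Zap70 (-0.49 ± 0.15, adjusted p = 0.0139; 0.053 without anti-CD40L week 8 replicate 1). Of 13 parotid and sublingual products 4 fell, and 4 when adjusted over the list alone (median -0.60, camera adjusted p = 0.039; 0.897 with an estimated correlation). These included Bpifb1 (-5.14 ± 1.72, adjusted p = 0.0222; 0.0521 without anti-CD40L week 16 replicate 1) and Prpmp5 (-3.62 ± 1.15, adjusted p = 0.0173; 0.0598 without anti-CD40L week 8 replicate 1). Quantile normalization ended the T cell (adjusted p = 0.127) and parotid (adjusted p = 0.246) calls. Amy1 was 13.42 (SD 0.222) at week 8 and 9.86 (SD 2.36) at week 16 (exact permutation p = 0.00794, adjusted p = 0.0278).

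Outside the lists, Myot (2.68 ± 0.36, adjusted p = 2.43e-05) and Lypd6b (2.53 ± 0.39) rose most from week 8 to week 16 after anti-CD40L, and the milk protein Csn3 (-3.06 ± 0.83, adjusted p = 0.00696) and the claudin Cldn22 (-3.20 ± 0.93, adjusted p = 0.0101) were among the largest falls. Cd40 fell by 0.55 ± 0.16 (adjusted p = 0.00904), in all 5 arrays. In total 4750 genes passed, 3127 higher and 1623 lower, and 4392 after quantile normalization, 1710 higher and 2682 lower. The count was 3138 without anti-CD40L week 8 replicate 1, and 3387 with the 3' minus 5' difference as a covariate, 3180 of them among the 4750.

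From week 8 to week 24 after anti-CD40L, antibody genes rose from their low start. Igha rose by 3.93 ± 0.27 (adjusted p = 1.15e-10), Igkv8-30 by 3.80 ± 0.29 (adjusted p = 1.32e-09), Jchain by 3.52 ± 0.34 (adjusted p = 1.53e-07) and Igk by 2.10 ± 0.23 (adjusted p = 1.68e-06), all with every week 24 array above every week 8 array. The mean level of the immunoglobulin list in treated glands was 7.23, 8.12 and 9.28 at weeks 8, 16 and 24, against 8.73, 10.24 and 11.44 in controls. Of 6 immunoglobulin genes 4 rose, and 4 when adjusted over the list alone (median 2.18, camera adjusted p = 0.000247; adjusted p = 0.601 with an estimated correlation). Of 13 myoepithelial and smooth muscle genes 9 rose, 11 when adjusted over the list alone (median 0.53, camera adjusted p = 0.00249; adjusted p = 0.883 with an estimated correlation), Mylk by 1.07 ± 0.19 and Actg2 by 0.96 ± 0.24. Of 20 ductal genes 8 rose, and 8 when adjusted over the list alone (median 0.33, camera adjusted p = 0.0111; adjusted p = 0.883 with an estimated correlation), Foxi1 by 1.13 ± 0.22 and Slc9a3 by 0.88 ± 0.21. Of 11 granular duct genes 6 rose, 8 when adjusted over the list alone (median 0.38, camera adjusted p = 0.0131; adjusted p = 0.888 with an estimated correlation), Klk1b24 by 0.82 ± 0.18. Of 18 unfolded protein response genes 9 rose, 10 and 1 falling when adjusted over the list alone (median 0.31, camera adjusted p = 0.00715; adjusted p = 0.883 with an estimated correlation), Sel1l by 0.82 ± 0.19.

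T cell genes fell from week 8 to week 24 after anti-CD40L in 2 of 11 members, and 2 when adjusted over the list alone, Cd4 by 1.13 ± 0.29 (adjusted p = 0.00876), with a list median of -0.23 (camera adjusted p = 0.0317; adjusted p = 0.883 with an estimated correlation; 0.146 after quantile normalization). Of 13 parotid products 2 fell, and 2 when adjusted over the list alone (median -1.78, camera adjusted p = 0.00117). This list gave adjusted p = 0.883 with an estimated correlation. Amy1 was 13.42 at week 8 and 10.43 (SD 2.88) at week 24 (exact permutation p = 0.0397, adjusted p = 0.0926). 5530400C23Rik (-4.43 ± 0.48) and the phosphatase Dusp1 (-1.87 ± 0.52, adjusted p = 0.0137) had the largest falls among genes past the threshold, and Cd40 did not pass (-0.38 ± 0.16, adjusted p = 0.0763). In total 3074 genes passed, 2148 higher and 926 lower, and 2897 after quantile normalization, 1240 higher and 1657 lower. The 3' minus 5' difference was 0.20 at week 24 and 0.369 at week 8 (exact permutation p = 0.00794, adjusted p = 0.0278). With it as a covariate 633 genes passed, 578 of them among the 3074. The count was 1381 and 1516 without anti-CD40L week 8 replicates 1 and 3.

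Whether the effect of the antibody differed between ages was tested by interaction terms. From week 8 to week 16 the effect moved up for Arntl (2.20 ± 0.44, adjusted p = 0.043) and the phosphatase Dusp6 (1.02 ± 0.20, adjusted p = 0.0342) and down for Cpxm1, a carboxypeptidase of the matrix (-1.76 ± 0.31, adjusted p = 0.0231), Clec3b, or tetranectin (-1.20 ± 0.23, adjusted p = 0.0342), and Nr1d2, a repressor of the clock (-0.95 ± 0.20, adjusted p = 0.0491). By camera 10 lists moved, none of which held with an estimated correlation (adjusted p = 0.501, except interferon gamma with 0.554 and fibroblasts with 0.453). MHC class II genes moved down (median -0.83, camera adjusted p = 2.53e-05), with 4 of 10 lower when adjusted over the list alone, and so did fibroblast and matrix genes (median -0.57, camera adjusted p = 5.74e-09; 7 of 18). Cell division genes moved up (median 1.24, camera adjusted p = 8.93e-10; adjusted p = 0.501 with an estimated correlation), 16 of 19 higher and 1 lower when adjusted over the list alone. Lower too were B cells (median -0.36, camera adjusted p = 0.0258), immunoglobulin genes (-0.58, 0.0402, with 1 of 6 lower when adjusted over the list alone), interferon gamma (-0.38, 0.0135), cytotoxic cells (-0.33, 0.0135), macrophages (-0.42, 0.00379), granular duct products (-0.25, 0.0127) and the clock list (-0.55, 0.0025). In the clock list 1 gene rose and 1 fell, 1 and 5 when adjusted over the list alone.

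In total 19 genes passed for the change from week 8 to week 16, 16 higher and 3 lower, 1771 had an unadjusted p under 0.05, and 57 passed after quantile normalization, 31 higher and 26 lower. Array weights gave 263, 128 higher and 135 lower, and fitting only the 20 arrays compared gave 39, without Nr1d2 (adjusted p = 0.0511). The named calls ended without 5 or more of the 20 arrays. The highest adjusted p was 0.0913 for Arntl, 0.0794 for Cpxm1 and 0.117 for Nr1d2 without anti-CD40L week 16 replicate 5, and 0.0881 for Dusp6 and 0.0859 for Clec3b without control week 16 replicate 2. The count was 0 without anti-CD40L week 8 replicate 4 or 5, anti-CD40L week 16 replicate 5 or control week 16 replicate 2. It was 1, 6, 2 and 10 without control week 16 replicates 1, 3, 4 and 5, 32, 4 and 6 without control week 8 replicates 2, 3 and 4, 7 without anti-CD40L week 8 replicate 1 and 52 without anti-CD40L week 16 replicate 2.

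From week 8 to week 24 the effect moved down for 14 lists, and 5 of these calls held with an estimated correlation. The B cell median was -0.89 (camera adjusted p = 3.8e-19; adjusted p = 0.00528 with an estimated correlation), with 11 of 15 genes lower when adjusted over the list alone and Ms4a1 at -3.34 ± 0.83 (adjusted p = 0.272) and Cd79b at -2.33 ± 0.51 (adjusted p = 0.102). The T cell median was -0.62 (camera adjusted p = 3.63e-10; adjusted p = 0.015 with an estimated correlation; 6 of 11), the plasma cell median -0.17 (camera adjusted p = 1e-05; adjusted p = 0.015 with an estimated correlation; 4 of 12), the naive lymphocyte median -0.45 (camera adjusted p = 0.000511; adjusted p = 0.0324 with an estimated correlation) and that of the CD40 and NF-kB response -0.27 (camera adjusted p = 4.69e-05; adjusted p = 0.0324 with an estimated correlation). MHC class II (median -0.85, camera adjusted p = 6.64e-10; adjusted p = 0.0822 with an estimated correlation; 4 of 10) and skeletal muscle (-0.50, 8.85e-06; adjusted p = 0.0609 with an estimated correlation; 3 of 9) were lower as well. The remaining lists that moved down were lymphoid chemokines (-0.36, 0.0023), type I interferon (-0.53, 4.78e-05), interferon gamma (-0.51, 1.65e-05), cytotoxic cells (-0.37, 0.00012), macrophages (-0.27, 0.00243), neutrophils (-0.12, 0.0156; 0.0661 after quantile normalization) and parotid products (-1.51, 0.00243). Their adjusted p with an estimated correlation was 0.104, 0.366, 0.366, 0.235, 0.367, 0.291 and 0.366. Ductal genes (0.22, camera adjusted p = 0.000244; adjusted p = 0.291 with an estimated correlation) and cell division genes (0.37, camera adjusted p = 0.0386; adjusted p = 0.642 with an estimated correlation) moved up.

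By single genes 1 of 12998 passed for the change from week 8 to week 24, and 759 had an unadjusted p under 0.05. It was Prg2 (-1.84 ± 0.31, adjusted p = 0.0302; 0.0505 when only the 20 arrays compared were fitted), and its call ended without 12 of the 20 arrays (highest adjusted p = 0.107, without anti-CD40L week 24 replicate 1). The count was 0 without control week 8 replicates 1 and 5, without each of the 5 anti-CD40L week 8 replicates, control week 24 replicates 3 and 5, and anti-CD40L week 24 replicates 1, 4 and 5. It was 2 without control week 8 replicate 2 or 4 or control week 24 replicate 2, 9 without control week 24 replicate 4 and 7 without anti-CD40L week 24 replicate 2.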

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

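The tests of lymph node tissue, of why B cell calls ended with the covariate, of collection time for the clock genes, of single arrays, of dividing lymphocytes and of the index of the splits were chosen only after the result was seen, as was the 3' minus 5' covariate of the RNA quality tests. Those of collection time for the cell division genes and of the number of genes in other splits of the arrays were set before it.

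Samples far from the others of their group were looked for among 198 groups of 5 values, made of the lists and quality measures. There were 9 such samples against 9.9 expected by chance, which picks about 1 in 20 groups. The mean interferon gamma level was 8.25 in control week 8 replicate 3 and 7.82 in anti-CD40L week 24 replicate 2. The latter also had a skeletal muscle level of 6.75, against 5.81 to 5.92 in the other arrays of its group. Control week 16 replicate 5 had a low level of granular duct products (12.91) and a high level of ductal genes (8.97). The unfolded protein response level was 10.36 in control week 16 replicate 4 and 10.71 in anti-CD40L week 16 replicate 4. Control week 24 replicate 1 had a mean clock gene level of 6.87 and a clock difference of -0.78, against -2.50 to -2.08 in the other 4.

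The effect of anti-CD40L differed between week 8 and week 16, by the test of the difference itself, for 19 genes. It moved up for Arntl (2.20), Ugt8a (1.48), Slc36a4 (1.34), Ezhip (1.23), Dnajc12 (1.14), 5033430I15Rik (1.04), Zfp810 (1.03), Dusp6 (1.02), Zfp938 (0.98), Steap1 (0.94), Hdhd3 (0.93), Nme1 (0.91), Pmvk (0.88), H1f2 (0.81), 2810410L24Rik (0.69) and Gm9958 (0.63), and down for Cpxm1 (-1.76), Clec3b (-1.20) and Nr1d2 (-0.95). Without 1 array the adjusted p reached 0.117 for Ugt8a, Slc36a4, 5033430I15Rik and Zfp810 (anti-CD40L week 16 replicate 5), 0.0894 for Ezhip (anti-CD40L week 8 replicate 4) and 0.0878 for Dnajc12 (control week 16 replicate 2). It also differed for 10 lists, with medians of -0.36 for B cells, -0.58 for immunoglobulin genes, -0.83 for MHC class II, -0.38 for interferon gamma, -0.33 for cytotoxic cells, -0.42 for macrophages, 1.24 for cell division, -0.25 for granular duct products, -0.57 for fibroblasts and -0.55 for the clock. None held with an estimated correlation (adjusted p = 0.453 to 0.554). Between weeks 8 and 24 it differed for the gene Prg2 (-1.84) and for 16 lists. Their medians were -0.89 for B cells, -0.17 for plasma cells, -0.62 for T cells, -0.36 for lymphoid chemokines, -0.45 for naive lymphocytes, -0.27 for the CD40 and NF-kB response, -0.85 for MHC class II, -0.53 for type I interferon, -0.51 for interferon gamma, -0.37 for cytotoxic cells, -0.27 for macrophages, -0.12 for neutrophils, 0.37 for cell division, -1.51 for parotid products, 0.22 for ductal genes and -0.50 for skeletal muscle. With an estimated correlation 5 of the 16 held, as named above, and the other 11 gave adjusted p = 0.0609 to 0.642.

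Probe sets with several genes or no gene, which the comparisons did not use, also differed between anti-CD40L and control. Of 3274 such probe sets above the filter, 4 passed adjusted p 0.05 at week 8, 62 at week 16 and 153 at week 24.

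The B cell genes were lower at week 24 after anti-CD40L. With the 3' minus 5' difference as a covariate the list median was -1.03, against -0.98 without it. All 15 genes lay below 0 with it (camera adjusted p = 2.55e-16 at the preset correlation). The 3' minus 5' difference did not overlap between the groups at week 24, so the covariate extends a slope taken within groups. A linear effect of that slope does not account for the falls, but this fit cannot separate RNA quality from treatment. Of the 11 genes called before, 3 passed with the covariate. The median change of the 11 was -1.25 with it and -1.19 without, and the median standard error of the list members went from 0.23 to 0.264. Of the 8 lost calls, 7 had an unadjusted p that would have passed without the covariate, where the largest p past the threshold was 0.00473 against 8.08e-05 with it. Lymph node tissue dissected with the control glands stays open. The naive lymphocyte and lymph node macrophage list had a median of -0.38 (standard error of its mean level difference 0.14 over the arrays), and the lymph node vessel marker Glycam1 gave -1.82 ± 0.80 (adjusted p = 0.127) while Madcam1 gave -0.02 ± 0.15, so node tissue and lymphocytes gathering within the gland cannot be told apart. A biological effect of the antibody on B cells may be the reason, which was not tested separately.

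Clock genes differed between treatments at weeks 16 and 24. Collection at another time of day is a candidate explanation: with Arntl and Dbp, whose changes gave the prediction, left out, 11 of 11 genes with a known phase lay on the predicted side at week 16 and 10 at week 24. These genes and their phases were also chosen after the values were seen, so the tally is weak evidence; their difference was 1.09 at week 16 (two-sided exact permutation p = 0.00794) and 0.68 at week 24 (exact permutation p = 0.0317). Over all 13 the clock difference averaged -0.79, -1.58 and -1.97 in controls at weeks 8, 16 and 24, and -0.96, 0.28 and -0.91 after anti-CD40L. By week 24 only the control mean had moved. Treated minus control was -0.17, 1.87 and 1.06 (exact permutation p = 0.54, 0.00794 and 0.0317, adjusted over the 3 ages 0.54, 0.0238 and 0.0475). With the 3' minus 5' covariate it was 1.88 ± 0.35 and 1.15 ± 0.40 at weeks 16 and 24 (SE 0.34 without). This argues against RNA quality as the cause. The labels give no collection times, and a change of the gland's own clock after treatment stays open and untested.

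The cell division genes were higher at week 16 after anti-CD40L. That 1 array carries the rise could not be excluded: the lowest list median without 1 of the treated arrays was 0.67 (without replicate 5; 1.13 with all), and the test of the mean level of the list against controls then missed 0.05 (exact permutation p = 0.0556; 0.0397 with all arrays, 0.0476 without replicate 1, 2 or 3 and 0.00794 without replicate 4). The highest camera adjusted p without 1 array was 5.5e-12, but with all arrays the list gave adjusted p = 0.14 with an estimated correlation. The number of members past the threshold was 5, 2, 5, 13 and 2 without replicates 1 to 5. More dividing lymphocytes could not be excluded either. The B cell list had a median of -0.29 and its mean level differed by -0.41 (standard error over the arrays 0.21, exact permutation p = 0.0317), and the T cell list had -0.35 and -0.39 (standard error 0.20, exact permutation p = 0.0873). A small share of dividing cells need not raise these levels, and within groups the lymphocyte level and the cell division level had r = 0.30 (95% bounds -0.11 to 0.62). Collection time may play a part and cannot be told apart from treatment: within groups the clock difference and the cell division level had r = 0.02 (permutation p = 0.945; Spearman rho = -0.10, permutation p = 0.666; 95% bounds -0.38 to 0.41; r = -0.03 without the 2 farthest arrays), which is too wide to exclude it. Proliferation of gland cells after the antibody stays open as an untested biological explanation.

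Other splits of the same arrays into groups of the same sizes were drawn, 100 for each comparison. At week 8 chance cannot be excluded, as 9 of 100 splits gave as many genes as the real 9, and the highest other gave 3786. The same holds in controls from week 8 to week 24 (8 splits; real 1624, highest other 4866) and for the change of the effect from week 8 to week 24 (14 splits; real 1, highest other 2586). Chance can be excluded at week 16 (1 split, the real one; real 245, highest other 14), at week 24 (1; real 1229, highest other 333), in controls from week 8 to week 16 (1; real 6046, highest other 4653) and after anti-CD40L from week 8 to week 16 (1; real 4750, highest other 1266) and to week 24 (1; real 3074, highest other 1399). For the change to week 16, 2 splits, the real one included, gave as many genes (real 19, highest other 891). For both changes, permuting treatment within each age removes both effects, so it cannot test their difference. The 19 are not stable: 0 passed with the 3' minus 5' difference as a covariate and without some single arrays, named above. The splits that called several times the real count, at week 8, in controls to week 24 and in both changes of the effect, point to a structure of the samples. The first principal component of the arrays held 41.7% of the variance and had r = -0.883 with the 3' minus 5' difference. The split with the most genes had the second largest difference of this index among the 99 other splits at week 8 (0.229) and for the change to week 16 (0.245), and the largest in controls to week 24 (0.261) and for the change to week 24 (0.332). Over those splits the count and the index difference had Spearman rho = 0.38, 0.074, 0.58 and 0.22, in the same order. A count above that of all other splits therefore leaves RNA quality open: the real index difference at week 24, 0.205, was above that of every other split (at most 0.164).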

How the results depend on the processing

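Only the covariates and the fit without the 5 arrays of low correlation were chosen after the data were seen. The fit reported called 9, 245 and 1229 genes for anti-CD40L at weeks 8, 16 and 24, and 16 lists at week 24. Unless a reason is given, the cause was not tested.

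Centring each array on its median left every count of genes and of lists within 1.5 times its value. Quantile normalization moved the change of the effect from week 8 to week 16 to 57 genes, and the lists passing to 4 at week 8, 9 in controls to week 16 and 2 after anti-CD40L to week 16. With no filter 12 lists passed in controls to week 16. The stricter filter tested fewer genes; lists passing were 1 at week 8, 8 at week 16 and 1 in controls to week 16, and the changes of the effect had 33 genes to week 16 and 0 to week 24. With the median over probe sets 4 genes and 1 list passed at week 8, 2 lists after anti-CD40L to week 16 and 2 genes for the change to week 24. There Cxcl12 at week 16 reversed to 0.37, as its probe sets differ in sign. Testing every probe set, which tests more features, gave 439 at week 16, 1987 at week 24, 11904 and 3314 in controls to weeks 16 and 24, 9384 and 5998 after anti-CD40L, and 3 for the change to week 24.

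Fitting only the arrays of the groups compared gave 0 genes at week 8, 965 at week 16, 129 at week 24, 41 in controls to week 24 and 39 for the change to week 16. Array weights gave 43 genes at week 8, 1557 at week 16, 263 for the change to week 16 and 0 for the change to week 24, with 1 list in controls to week 16 and 6 for the change to week 16. Trend and robust estimation gave 29 genes for the change to week 16. A fold change of at least 1.5 as well, which can only lower a count, left 158 and 607 genes at weeks 16 and 24, 2369 and 636 in controls and 1668 and 1062 after anti-CD40L. A threshold of 0.1, which can only raise it, gave 524 and 2482 at weeks 16 and 24, 2730 in controls to week 24, and 140 and 7 for the changes to weeks 16 and 24.

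The replicate numbers do not pair the samples: correlations of arrays with the same number, after removing group means, ran from -0.633 to 0.401. As a block they gave 4 genes at week 8, 2 and 0 for the changes to weeks 16 and 24, and 3 lists in controls to week 16.

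Camera with an estimated correlation passed 0, 1 and 4 lists at weeks 8, 16 and 24, 0 and 2 in controls to weeks 16 and 24, 0 and 0 after anti-CD40L, and 0 and 5 for the changes of the effect. With fry, which does not compare a list with other genes, it was 1 at week 8, 7 at week 16, 14 in controls to week 16, and 0 and 3 for the changes to weeks 16 and 24.

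With the 3' minus 5' difference as a covariate 3 genes passed at week 8, 450 at week 16 and 23 at week 24, 620 and 715 in controls to weeks 16 and 24, 633 after anti-CD40L to week 24 and 0 for the change to week 16, and 11 lists in controls and 2 after anti-CD40L to week 16. With the Amy1 level it was 20 genes at week 8, 1888 at week 24, 2658 and 1412 after anti-CD40L to weeks 16 and 24, and 89 and 2 for the changes, with 3 lists in controls to week 16 and 6 for the change to week 16. Without the 5 arrays of low correlation, which are control week 8 replicates 3 and 4, anti-CD40L week 8 replicates 1 and 3 and control week 24 replicate 1, it was 36 genes at week 8, 670 at week 16, 2476 and 1110 after anti-CD40L, and 50 and 0 for the changes.

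Leaving out 1 array gave 4 to 23 genes at week 8, 74 to 220 at week 16, 237 to 2140 at week 24, 4444 to 6781 and 721 to 3228 in controls, 3138 to 5297 and 1381 to 3793 after anti-CD40L, and 0 to 52 and 0 to 9 for the changes. The lists passing ran from 1 to 3, 13 to 16 and 15 to 20 for treatment at the 3 ages, 1 to 8 and 10 to 18 in controls, 3 to 5 and 5 to 7 after anti-CD40L, and 5 to 13 and 14 to 18 for the changes.

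Among the named genes, counted once per comparison, quantile normalization kept the direction and side of the threshold for 175 and ended 7 calls, the model of only the groups compared kept 124, ended 56 and added 2, and the 3' minus 5' covariate kept 102 and ended 80. Trend and robust estimation kept all 182. Over all fits without 1 array 1588 values kept their side, 367 lost it and 5 gained it, and none reversed. A floor of 32 was not run, as the values are log2. Signal over background limits genes of low level such as Cd40lg, which the filter left out.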

Other observations

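Each hypothesis tested is weighed under the results for a closer look. The values here are levels of genes, lists and controls over the arrays; the parotid genes and bioB were chosen only after their values were seen, and the lists were fixed before.

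Parotid products differed widely from gland to gland. Over the 30 arrays the log2 level of Bpifb1 went from 5.836 to 13.779, of Dnase1 from 6.274 to 14.07, of Amy1 from 6.575 to 13.695 and of Prpmp5, a proline-rich protein, from 3.279 to 9.097. Amy1 was above a log2 level of 10 in 17 of the 30 arrays, Dnase1 in 16 and Bpifb1 in 14. Amy1 lay between 13.18 and 13.70 in the 5 anti-CD40L arrays of week 8 and between 6.575 and 13.60 in their controls.

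Immunoglobulin levels of the treatments did not overlap at any age. The mean level of the list lay between 7.02 and 7.50 in the anti-CD40L arrays at week 8 against 7.55 to 9.83 in controls, between 7.71 and 8.57 against 9.54 to 11.21 at week 16, and between 8.62 and 10.04 against 10.93 to 11.92 at week 24. The B cell list spread over 6.10 to 7.54 in the 5 control arrays of week 24 and over 5.54 to 5.78 in the anti-CD40L arrays. The T cell list spread over 6.63 to 7.47 and 5.86 to 6.44.

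The spiked hybridization control bioB was also uneven between ages. The arrays are on a common scale, with medians of 5.487 to 5.537, so its value is relative to the mouse signal. It averaged 11.38 in control arrays and 11.10 in anti-CD40L arrays at week 8, 10.52 and 10.43 at week 16 and 10.80 and 10.42 at week 24. Week 16 against week 8 gave an exact permutation p of 0.00794 in both treatments (adjusted p = 0.0278). The labels give no scan or hybridization batch, so neither age nor treatment can be separated from batch by them. Whether bioB differs through batch or through RNA quality was not tested.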
